A study of Drosophila melanogaster with 12 samples.

How the data were processed

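Whole Drosophila melanogaster of the outbred laboratory population LHm, kept at 25 °C, were measured as 6 groups: females and males, each as larvae of the third instar, pupae and adults. Each group had 2 biological replicates of 10 animals, which gave 12 arrays. Per the labels' protocols, vials were set up at staggered times so that animals of all stages were collected together, total RNA was extracted with a commercial kit, and biotin-labelled target was hybridised to Affymetrix Drosophila Genome 2.0 arrays, which measure each transcript with sets of short probes.

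The authors deposited 1 table of log2 expression values, 1 value per probe set and array. RMA, a procedure that corrects background, normalizes arrays and summarises the probes of a set, is named in the submitters' processing notes. Its version and options are not given in the sources used here. The table held 18952 probe sets with no missing value, between 2.47 and 15.61 on the log2 scale. The 183 control probe sets were left out of all tests, which leaves 18769. Values near the lower end of this range lie close to the background of the arrays, so differences from such a level are compressed. The number of arrays limits the precision.

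Genes were named from the platform annotation given with the series and from RefSeq names of assembly Release 6. Of the 18769 probe sets, 13646 carried 1 gene, 402 carried several and 4721 were unnamed here. The reference table held the gene of 13543 of the 1-gene probe sets, and no symbol needed an update. Only probe sets with 1 gene were named. For 11982 genes the probe set with the highest mean over the 12 arrays stands for the gene, and 1094 of them had over 1 probe set. The reference was used for names and for the chromosome a gene lies on.

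Differences were tested with limma (version 3.58.1) in R (version 4.3.3). A single fit of 6 group means used all 12 arrays, with 6 residual degrees of freedom and 4.1 prior degrees of freedom from eBayes without a trend. The 9 comparisons were the sex difference at each stage (female minus male), the step from larvae to pupae and from pupae to adults within each sex, and the change of the sex difference over each step. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. All adjusted p-values in the text are from this limma test unless another test is named. A value after ± is the standard error (SE) of a log2 difference. After a group mean, where stated, it is the standard deviation (SD) between the arrays of that group. Each group had n = 2 arrays.

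Before the data were examined, 19 gene lists were written from general knowledge. They held 685 entries, of which 514 were measured by a probe set of 1 gene, and no gene was in over 1 list. In 8 lists under 80% of the entries were measured, among them heat shock (8 of 20), ribosomal proteins (22 of 63) and antimicrobial (17 of 34). Lists were tested against all other genes with camera at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the 19 lists of a comparison. The same test was run with the correlation estimated from the data. The fry test, which asks whether the members of a list move one way on balance without a comparison with other genes, was run beside it. Its results are given only for some lists that did not pass the camera test. Members were counted as called over all probe sets and adjusted over the list alone.

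The rule for named genes was also set beforehand. Per comparison it took the 6 genes with the largest positive and the 6 with the largest negative difference, called and with both arrays of one group above both of the other. For the 2 changes of the sex difference it took 4 in each direction without the condition on arrays. It added up to 3 called members of each list with the largest difference, and in each comparison msl-2, Sxl, tra, dsx, Yp1, Yp2 and Yp3. The roX genes of the rule were matched to no probe set and were not analysed here. A gene that falls outside this rule is said to be so where it is named.

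Overlap of sex bias between stages was counted over genes and direction and set beside the number for independent lists. X-linked and autosomal genes were compared between sex-biased genes and genes not called with a two-sided Fisher's exact test over 11823 genes on X or an arm of the 2 large autosomes, adjusted over 6 tests.

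The alternatives set beforehand were quantile normalization, centring on array medians, a filter on dim probe sets, a fit of only the groups compared, a replicate block, eBayes with trend and robust, 1 probe set per gene, a 2-fold minimum, and each array left out. One further alternative, called recentring below, was chosen after seeing the data: each array was centred on the median of its deviations from the probe set means. It was added because the median log2 difference over all probe sets was not 0 between the sexes.

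The tests were checked on simulated data for the sex difference in larvae with 200 changed probe sets among 18769. All 50 of log2 size 2 and all 50 of size 4 were called, with 43 of 50 of size 1 and 8 of 50 of size 0.5, and 10 unchanged probe sets were called. With 1 list moved, 1 of 19 lists was called. The simulated noise was independent between probe sets and had no shift between the sexes. The check therefore does not cover correlated genes or such a shift.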

Results

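Messenger RNA was measured on 12 arrays of whole female and male fruit flies as larvae, pupae and adults, with 2 arrays per group and 10 animals per array. The design asks how expression differs between the sexes at each stage, how it changes from stage to stage within a sex, and whether the sex difference itself changes. Arrays had mean values between 6.939 and 6.997 on the log2 scale. Array medians lay between 6.27 and 6.44 in females and between 6.73 and 6.81 in males. In each comparison 18769 probe sets were tested.

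Differences over all probe sets were not centred on 0 between the sexes. The median female minus male log2 difference was 0.23 in larvae, 0.37 in pupae and 0.21 in adults. After recentring, which brings this median near 0 largely by construction, it was 0.04, 0.10 and -0.04. Under array-median centring it was larger, 0.60, 0.74 and 0.68. Bacterial control transcripts, which are added to the hybridisation mix, were also higher on female than on male arrays in larvae (median difference 0.43) and pupae (0.73), and differed by 0.011 in adults. Small sex differences are therefore given beside these shifts. Between stages of 1 sex the median difference stayed between -0.07 and 0.03.

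**Figure D1:**
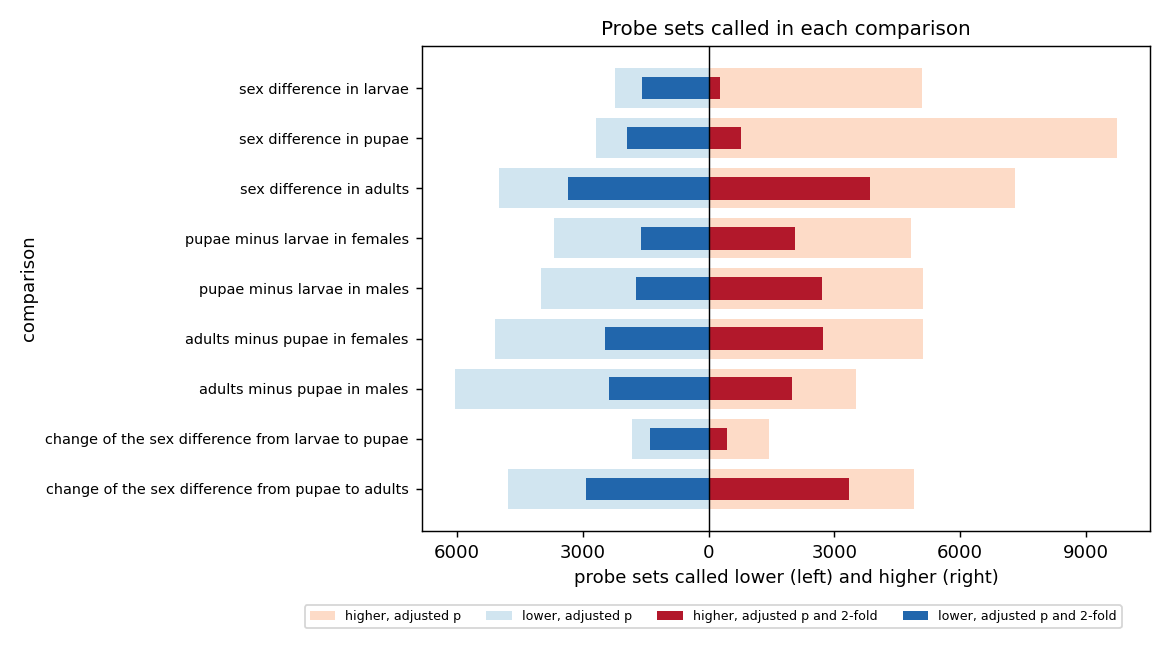
Bars give the number of probe sets called lower (left) and higher (right) in each of 9 comparisons, with paler bars for an adjusted p under 0.05 and darker bars for those that also differ at least 2-fold. In larvae 5091 probe sets were called higher in females, 269 of them by at least 2-fold.

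The first comparison asked which transcripts differ between the sexes in larvae. Genes of the testis were far higher in male larvae, and a yolk protein gene had the largest female-higher difference. The largest male-higher differences, given as female minus male, were -8.29 ± 0.19 for CG9920 (adjusted p = 5.6e-10), -7.92 ± 0.12 for lncRNA:CR32690, -7.74 ± 0.21 for fest, -7.62 ± 0.14 for ocn, -7.50 ± 0.21 for TrxT and -7.44 ± 0.29 for CG31226. Of the 53 measured members of the testis and spermatogenesis list, 47 were lower in females and 0 higher, with a median difference of -2.99 (camera adjusted p = 2.11e-30, and 0.00729 with an estimated correlation). Among them were Mst77F, which encodes a sperm chromatin protein (-6.85 ± 0.16), and betaTub85D, a testis-specific tubulin (-6.73 ± 0.20). Adjusted over the list alone, the count was also 47 lower. Several genes of the ovary and maternal list also had higher levels in males at this stage, among them bgcn (-2.78 ± 0.23), mael (-2.73 ± 0.14) and exu (-2.57 ± 0.12). A second exu probe set had a larger difference in the same direction (-7.1). In that list 11 of 37 members were lower in females and 3 higher, and the list as a whole did not pass the camera test (adjusted p = 0.13). Its median was 0.03, whereas its mean (-0.28) and the direction of its camera test were negative. The fry test of this list gave an adjusted p = 0.00265.

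By at least 16-fold, 2 probe sets were higher in female larvae and 307 lower. Yp3, which encodes a yolk protein, had the largest female-higher difference of the named genes, 4.73 ± 0.17 (adjusted p = 5.72e-09), with a mean of 10.07 ± 0.26 (SD) in females and 5.34 ± 0.32 (SD) in males. The other yolk protein genes were at low levels in both sexes, with means of 4.46 and 4.29 for Yp1 (adjusted p = 0.686) and 6.17 and 5.66 for Yp2. The Yp2 difference of 0.51 ± 0.16 passed the test (adjusted p = 0.0321) but not after recentring (0.33, adjusted p = 0.16). TotC, a stress-induced gene, was higher in females by 3.47 ± 0.26, hll by 2.82 ± 0.28, CG4830 by 2.64 ± 0.39 and ng1, a gene of the salivary gland, by 2.47 ± 0.20. CG42717 differed by 2.28 ± 0.56 (adjusted p = 0.0104), and this call was lost without female larvae replicate 1, without male larvae replicate 1 and in a fit of the compared groups alone. Digestive enzymes were called higher in females for 18 of 37 members, with lambdaTry at 1.49 ± 0.23, thetaTry at 1.42 ± 0.14 and kappaTry at 1.33 ± 0.22. That list had a camera adjusted p of 0.0179, and an adjusted p = 0.443 with an estimated correlation. After recentring 13 of its members were called higher and 0 lower, and adjusted over the list alone 18 were higher. Hemocyte genes were higher in 8 of 16 (median 0.37, adjusted p = 0.0286, and adjusted p = 0.443 with an estimated correlation), 5 of them after recentring.

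Of 18 genes of sex determination and dosage compensation, 3 were higher and 5 lower in female larvae (camera adjusted p = 0.749), with a median of 0.11 but a mean of -0.05. The transcript of msl-2, whose protein acts in male dosage compensation, was lower in females (-1.46 ± 0.12), and tra, the splicing factor active in females, was higher (1.11 ± 0.11). The gene dsx, spliced differently in the sexes, was read by 2 probe sets that gave opposite results: the brighter one was lower in female larvae (-1.10) and the other higher (4.54). In pupae these values were -0.85 and 5.67, and in adults -2.99 and 2.91. Sxl was read by 3 probe sets, and the brightest did not pass the test in larvae (0.26 ± 0.09, adjusted p = 0.0521) or in pupae (0.02 ± 0.09, adjusted p = 0.833). A second Sxl probe set was higher in females by 2.14 in larvae and 2.75 in pupae, and the third was not called (0.08 and 0.03).

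In all, 7318 probe sets were called between larvae of the 2 sexes, 5091 higher in females and 2227 lower. The split turned round at larger sizes, with 269 higher and 1582 lower by at least 2-fold. It also turned round after recentring, with 1400 higher and 2775 lower, and under array-median centring 14871 were higher and 1790 lower. When any single larval array was left out the count of calls fell, mainly among those higher in females. The fall was largest without male larvae replicate 2.

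The same question was asked of pupae. Testis genes were again far higher in males, and a group of genes was much higher in females. The largest male-higher differences were CG9920 at -10.05 ± 0.19 (adjusted p = 4.67e-11), CG31226 at -9.33 ± 0.29, ocn at -9.26 ± 0.14, CG17377 at -9.16 ± 0.25, Mst77F at -8.90 ± 0.16 and CG31988 at -8.76 ± 0.19. A second CG17377 probe set was not called (-0.36). Of the testis list, 49 of 53 members were lower in females and 1 higher (median -4.42, camera adjusted p = 6.2e-28, and 0.00921 with an estimated correlation), and adjusted over the list alone 50 were lower and 1 higher. Genes that act in germ cells or in cell division included members lower in female pupae, exu (-4.25 ± 0.12), bgcn (-3.72 ± 0.23), BicC (-2.90 ± 0.15), pim (-3.45 ± 0.11), fzy (-2.17 ± 0.10) and feo (-1.45 ± 0.11). A second fzy probe set was higher in female pupae, by 0.66, and the third was not called (0.01). For exu a second probe set had a larger difference in the same direction (-8.5). Over the ovary list 15 of 37 were higher and 9 lower (median 0.18, mean -0.17, adjusted p = 0.569), and over the mitosis list 19 of 34 were higher and 7 lower (adjusted p = 0.877). After recentring these counts turned to 7 higher and 11 lower in the ovary list and 7 higher and 10 lower in the mitosis list.

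The largest female-higher differences in pupae came from genes at low levels in male pupae. CG14624 was higher by 6.87 ± 0.15 (adjusted p = 9.49e-11), with a mean of 10.85 ± 0.20 (SD) in female pupae, 3.98 ± 0.19 (SD) in male pupae and at most 4.57 in the other groups. The next largest differences were 6.17 ± 0.46 for CG15615, 6.03 ± 0.17 for CG11693, 5.97 ± 0.26 for CG13154, 5.77 ± 0.24 for CG9083 and 5.46 ± 0.37 for CG15545. Pdh, a retinal dehydrogenase of the eye, was higher by 5.18 ± 0.13 and the pigmentation gene y by 4.94 ± 0.61. The light-activated channel gene trp was higher by 2.19 ± 0.18, whereas the arrestin gene Arr1 (-1.85 ± 0.14) and the cuticle gene Edg84A (-2.26 ± 0.15) were lower in females.

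Most gene lists had small female-higher medians in pupae. Muscle genes were called higher in 21 of 26 and lower in 0 (median 0.76), with Mf at 1.55 ± 0.15, Obsc at 1.21 ± 0.13 and Mlp84B at 1.16 ± 0.15. A second Obsc probe set was not called (0.18). Muscle had a camera adjusted p of 0.0155, and an adjusted p = 0.607 with an estimated correlation. Eye genes were called higher in 19 of 24 (median 0.72), pupal and adult cuticle genes in 16 of 24 (median 0.70) and neuronal genes in 23 of 30 (median 0.57), and these lists did not pass the camera test (adjusted p = 0.088, 0.251 and 0.123). By the fry test the adjusted p of these 3 lists was 3.56e-05, 0.000326 and 6.1e-05. Since fry does not compare a list with other genes, a shift over all probe sets can also move it. The control transcripts differed by a median of 0.73 in pupae, below the muscle median and above the other 3 medians. Single control probe sets ranged from 0.065 to 0.982, which spans all of these medians, so the order says little. After recentring 15 muscle, 11 eye, 11 cuticle and 8 neuronal members were called higher. Adjusted over the list alone the counts were 21, 19, 16 and 23. Lists of other kinds had medians of similar size, among them hemocyte (0.56, 13 of 16 higher), antimicrobial (0.55, 7 of 17), digestive enzymes (0.52, 20 of 37), larval cuticle (0.52, 9 of 19) and yolk and eggshell genes (0.48, 15 of 24), and none of these 5 passed the camera test (adjusted p = 0.123, 0.502, 0.251, 0.502 and 0.285). Even accessory gland genes were called higher in 20 of 36 and lower in 2 (median 0.39, camera adjusted p = 0.275). After recentring 2 of them were called higher and 2 lower.

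Yp3 was higher in female pupae by 2.66 ± 0.17, tra by 1.37 ± 0.11 and TotC by 1.83 ± 0.26, and msl-2 was lower (-0.67 ± 0.12). Over all probe sets 9745 were called higher in female pupae and 2690 lower, 771 and 1949 of them by at least 2-fold. After recentring 3311 were higher and 3382 lower, and under array-median centring 15133 and 2172.

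In adults the sexes were compared with mature reproductive organs. Adult females had high levels of yolk, eggshell and ovary transcripts: Yp1 was higher by 10.01 ± 0.32 (adjusted p = 5.1e-10), the chorion gene Cp36 by 9.36 ± 0.22, Yp2 by 9.20 ± 0.16, osk, which organises the germ plasm, by 8.81 ± 0.19, dhd, a germline thioredoxin, by 8.71 ± 0.25 and Cp19 by 8.65 ± 0.13. All 24 yolk and eggshell genes were higher in females (median 7.04, camera adjusted p = 1.14e-09, and adjusted p = 0.0716 with an estimated correlation). Of the ovary and maternal list 36 of 37 were higher (median 4.25, adjusted p = 5.02e-10, and 0.0407 with an estimated correlation). All 34 genes of mitosis and DNA replication were higher (median 3.83, adjusted p = 2.56e-11, and 0.0335 with an estimated correlation), with RnrL at 6.72 ± 0.10, CycE at 6.36 ± 0.16 and Orc1 at 6.21 ± 0.12. All 22 ribosomal protein genes measured were higher by a smaller amount (median 1.00, adjusted p = 1.41e-05, and adjusted p = 0.114 with an estimated correlation), among them RpL34a (1.60 ± 0.10), RpL3 (1.33 ± 0.09) and RpLP0 (1.26 ± 0.09). Adjusted over the list alone the counts of these 4 lists were 24, 36, 34 and 22.

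Adult males had high levels of transcripts of seminal fluid proteins, with EbpII at -11.08 ± 0.17 (adjusted p = 7.28e-12), Ebp at -10.92 ± 0.16, Acp53C14a at -10.91 ± 0.13, Acp53Ea at -10.86 ± 0.09, Acp63F at -10.67 ± 0.18 and Acp53C14b at -10.29 ± 0.18. Of the accessory gland list 35 of 36 genes were lower in females and 0 higher (median -7.66, camera adjusted p = 5.82e-16, and 0.00354 with an estimated correlation). Of the testis list 47 of 53 were lower and 2 higher (median -4.48, adjusted p = 1.11e-12, and 0.0335 with an estimated correlation). Adjusted over the list alone 35 and 47 were lower.

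Transcripts of several other tissues were lower in adult females. Muscle genes were called lower in 25 of 26 and higher in 0 (median -1.56, camera adjusted p = 1.08e-06, and adjusted p = 0.0716 with an estimated correlation), with TpnC41C at -2.22 ± 0.14, Act79B at -2.01 ± 0.14 and Msp300 at -1.94 ± 0.13. Of the other Msp300 probe sets 1 was lower (-1.41), 1 was higher in females, by 0.45, and the rest were not called (-0.03, 0.36 and -0.16). Eye genes were lower in 20 of 24 (median -1.45, adjusted p = 0.000388, and adjusted p = 0.0716 with an estimated correlation), among them ninaD (-2.44 ± 0.30), Pdh (-2.18 ± 0.13) and chp (-1.89 ± 0.16). Genes of olfaction and taste were lower in 21 of 36 (median -0.84, adjusted p = 0.00286, and adjusted p = 0.132 with an estimated correlation), with the odorant-binding protein genes Obp99b at -4.08 ± 0.10, Obp44a at -3.96 ± 0.09 and Obp69a at -2.28 ± 0.13. Neuronal genes were lower in 18 of 30 (median -0.64, adjusted p = 0.00291, and adjusted p = 0.0716 with an estimated correlation), with Gad1, which makes the transmitter GABA, at -2.31 ± 0.12, Snap25 at -2.29 ± 0.12 and ChAT at -1.84 ± 0.09. Adjusted over the list alone 25 muscle, 20 eye, 21 olfactory and 18 neuronal genes were lower.

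Members of other lists went both ways in adults. Among digestive enzymes 5 were higher and 15 lower in females, with Jon66Ci at 2.83 ± 0.22, Jon66Cii at 2.00 ± 0.20 and Ser8 at -2.46 ± 0.18. The heat shock genes Hsp26 (3.62 ± 0.24), Hsp27 (3.35 ± 0.14) and Hsf (2.27 ± 0.10) were higher in females, with 6 of 8 measured members higher and an adjusted p of 0.0751 for the list. TotC, higher in females as larvae and pupae, was lower in adult females (-2.37 ± 0.26). The dosage compensation gene mof was higher in adult females (2.15 ± 0.14) and msl-2 lower (-0.98 ± 0.12). The brightest Sxl probe set was higher in adult females (1.23 ± 0.09) and the other Sxl probe sets were lower (-0.38 and -0.89). In all 7311 probe sets were called higher in adult females and 4999 lower, 3857 and 3356 by at least 2-fold. After recentring 5251 were higher and 6070 lower, and under array-median centring 12691 and 3771.

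**Figure D2:**
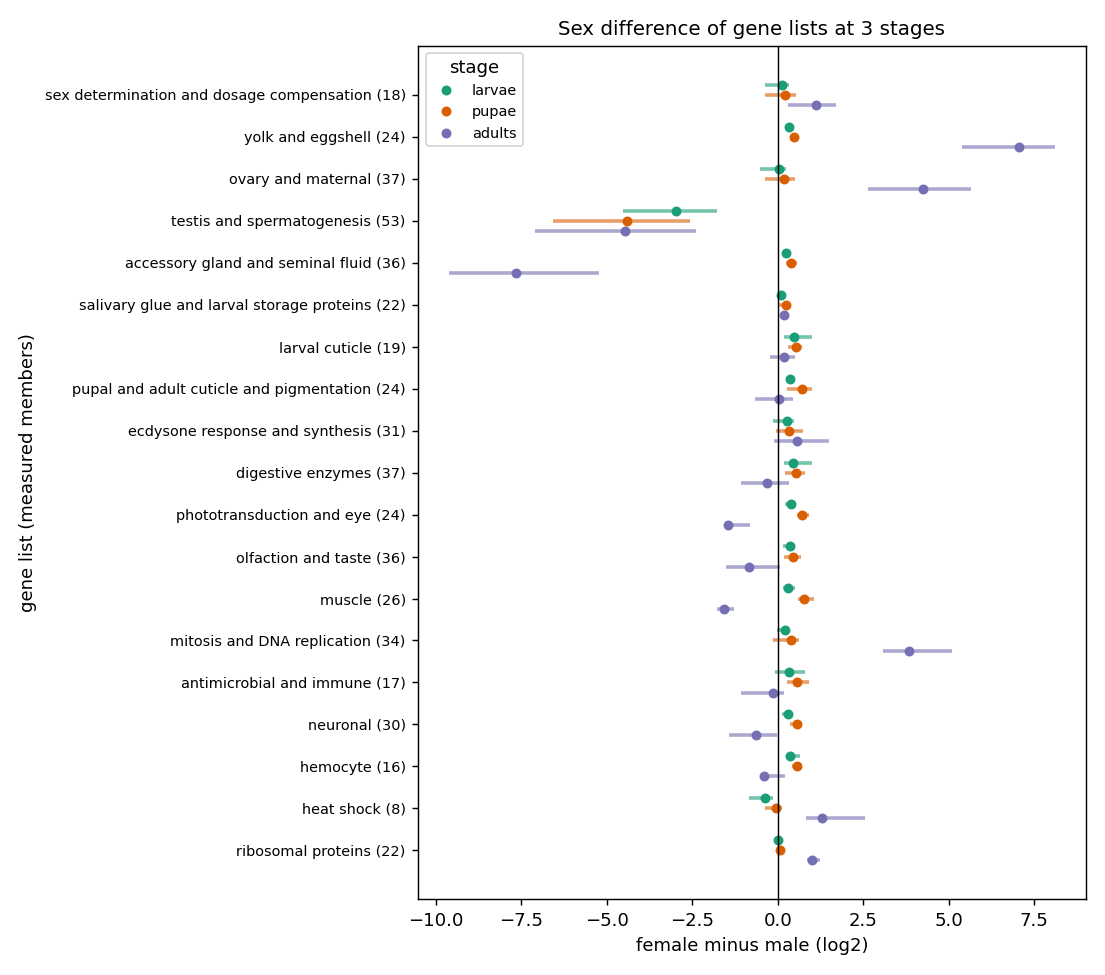
Points give the median female minus male log2 difference over the measured members of each gene list in larvae, pupae and adults, and lines span the quartiles. The testis list lies below 0 at each stage, with medians of -2.99, -4.42 and -4.48, whereas the yolk, ovary, mitosis and accessory gland lists lie far from 0 in adults.

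Sex bias was then compared between stages over 11982 genes. Across genes the female minus male differences of larvae and pupae had r = 0.92, those of pupae and adults 0.67 and those of larvae and adults 0.65, and genes are not independent replicates. At a 2-fold minimum 1394 genes were higher in males in both larvae and pupae, against 209 for independent lists. For pupae and adults the number was 1550 against 430. In female-higher genes the overlap of larvae and pupae was 50 against 12, and that of pupae and adults was 71 against 173. Without the 2-fold minimum these overlaps were 2233 against 1470 and 2990 against 2540, so the female-higher overlap of pupae and adults lay above or below the number for independent lists depending on the minimum. That of larvae and adults lay below it both with the minimum (14 against 61.9) and without (1124 against 1230). Without the minimum 1613 genes were higher in female pupae and lower in female adults, and 367 went the other way. With the minimum these counts were 159 and 52. Since 6027 of the 11982 genes were higher in female pupae and 4267 lower in female adults, independent lists would also share many. The count of 1613 is therefore no sign of a reversal by itself. The count of shared female-higher genes also changed with scaling and with single arrays: after recentring it was 410 for larvae and pupae, 855 for pupae and adults and 168 for larvae and adults. For larvae and pupae it was 1096 without male larvae replicate 2 and 1409 without male larvae replicate 1. For larvae and adults it was 493 and 607 without these arrays, and 734 and 693 without female larvae replicate 1 and 2. Calls within a stage fell too: after recentring female-higher probe sets went from 5091 to 1400 in larvae and from 9745 to 3311 in pupae. No number for independent lists is given under these settings, so the lower counts do not show weaker sharing. In all 3 stages 1346 genes were at least 2-fold higher in males and 6 in females. The 6 were Yp3, tra, hll, Cpr49Ah, fit and kar, of which the last 3 were chosen after their values were seen.

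The chromosomes of sex-biased genes were compared with those of genes not called. Female-higher genes were more often on X: 21.7% against 14.1% in larvae (odds ratio 1.69, 95% interval 1.51 to 1.89, Fisher's exact adjusted p = 5.3e-19), 18.5% against 13.1% in pupae (1.5, adjusted p = 2e-11) and 18.5% against 14.3% in adults (1.36, adjusted p = 5.46e-06). With a 2-fold minimum the odds ratio did not pass in larvae (1.34, adjusted p = 0.15) and passed in pupae (1.53) and adults (1.48). The share on X among male-higher genes did not differ by the test from that of genes not called (odds ratios 0.95, 1.02 and 0.94). The male-higher odds ratios passed the test under other settings. After recentring they were 0.765 in larvae (adjusted p = 8.79e-05) and 0.823 in pupae (adjusted p = 0.00339), and with the filter on dim probe sets 0.683 (adjusted p = 0.000318) and 0.794 (adjusted p = 0.0429). In larvae they also passed without female larvae replicate 2 (0.79, adjusted p = 0.00186) and without male larvae replicate 1 (0.843, adjusted p = 0.0341).

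The step from larvae to pupae was compared within each sex. In both sexes genes of the salivary glue and digestive enzymes were among the largest decreases, and the genes Osi12, Osi9 and Osi4 among the largest increases. In females Osi12 rose by 10.99 ± 0.15 (adjusted p = 1.01e-11), CG31606 by 10.43 ± 0.16, Osi9 by 10.07 ± 0.22, Osi4 by 9.84 ± 0.16, CG13720 by 9.27 ± 0.46 and CG42331 by 9.27 ± 0.13, whereas a second CG42331 probe set was not called (0.16). Osi12 had the highest values on the female pupal arrays (15.31 and 15.33), at the top of their range, so its exact size and rank are less certain. In males CG31606 rose by 10.56 ± 0.16, Osi9 by 10.28 ± 0.22, Osi12 by 10.25 ± 0.15, Osi4 by 9.61 ± 0.16, Osi22 by 9.51 ± 0.15 and dyl, a gene of the apical cell surface, by 9.40 ± 0.11. The glue genes Sgs4 and Sgs3 fell by 10.83 and 10.61 in females and by 11.53 and 10.63 in males. The proteases Jon99Fi and Jon65Aiv fell by 11.08 and 10.43 in females and by 10.63 and 10.22 in males. Sgs5bis fell by 10.07 in females and CG11854 fell by 9.87.

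Digestive enzymes fell in 33 of 37 members in each sex, with a median of -5.65 in females and -4.86 in males (camera adjusted p = 2.86e-16 and 2.72e-15, and adjusted p = 0.0718 and 0.0977 with an estimated correlation). Genes of mitosis and DNA replication fell in 29 of 34 in each sex, with medians of -1.19 and -1.13 (adjusted p = 1.64e-09 and 1.16e-08, and adjusted p = 0.0718 and 0.0977 with an estimated correlation). Among them pim fell by 3.00 and fzy by 2.33 in females, and RnrL by 2.19 and Mcm5 by 1.95 in males. A second fzy probe set rose in females, by 0.46, and the third was not called (-0.02). Eye genes rose in 18 of 24 in females and 15 of 24 in males (adjusted p = 9.49e-05 and 0.00223, and adjusted p = 0.0718 and 0.16 with an estimated correlation). Muscle genes went both ways, with 12 of 26 higher and 8 lower in females and 13 higher and 11 lower in males (adjusted p = 0.366 and 0.913). Among them Act88F rose by 8.93 ± 0.24 and TpnC4 by 8.62 ± 0.17 in females, and by 9.21 ± 0.24 and 8.21 ± 0.17 in males.

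Other groups changed in both directions or in part. In cuticle, Lcp9 fell by 8.14 in females, whereas Cpr66D rose by 7.30 ± 0.15. The ecdysone-responsive gene ImpL1 rose by 7.12 ± 0.12 in females and 7.95 ± 0.12 in males, and the transcription factor genes Kr-h1 and br fell by 4.75 and 4.35 in females and by 5.60 and 5.25 in males. The hemocyte genes He, PPO1 and PPO2 fell by 6.96, 5.96 and 5.24 in females, and the hemocyte list passed in males (8 of 16 lower and 4 higher, adjusted p = 0.038, and adjusted p = 0.44 with an estimated correlation). Glue and storage protein genes fell in 12 of 22 in each sex (adjusted p = 8.09e-05 in females and 0.000103 in males, and adjusted p = 0.0718 and 0.117 with an estimated correlation). Neuronal genes rose in 20 of 30 in females (adjusted p = 0.00118, and adjusted p = 0.0718 with an estimated correlation) and ribosomal protein genes in 6 of 22 (adjusted p = 0.0418, and adjusted p = 0.53 with an estimated correlation), the latter in 3 adjusted over the list alone. The neuronal gene futsch rose by 4.11 ± 0.15 in females and 4.41 ± 0.15 in males, while the other futsch probe sets were not called in females (-0.03 and 0.04), and in males 1 fell by 0.48 and 1 was not called (-0.16). The male-specific behaviour gene fru rose by 2.18 ± 0.17 in females and 3.31 ± 0.17 in males by its brightest probe set. Of the other fru probe sets, those called rose by 0.66 and 1.43 in females and by 1.16, 1.05, 1.11 and 1.77 in males, and those not called had values of -0.07, 0.38, 0.04 and 0.37 in females and 0.29 and 0.10 in males. Testis genes rose in 42 of 53 in males (median 1.53, adjusted p = 5.94e-06, and adjusted p = 0.117 with an estimated correlation), among them S-Lap7 by 2.29 ± 0.14, Mst84Db by 2.27 ± 0.21 and S-Lap8 by 2.23 ± 0.21. In females 5 of the 53 rose and 4 fell. In all 4831 probe sets rose and 3684 fell in females, and 5114 rose and 3982 fell in males.

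From pupae to adults digestive transcripts rose in both sexes, ovary and yolk transcripts rose in females and accessory gland transcripts in males. In females Jon99Fi rose by 10.22 ± 0.19 (adjusted p = 3.03e-11), Jon65Aiv by 9.81 ± 0.23, dhd by 9.24 ± 0.25, yip7 by 9.04 ± 0.20, CG4991 by 8.82 ± 0.20 and Yp1 by 8.76 ± 0.32. Digestive enzymes rose in 33 of 37 members in each sex, with medians of 3.77 in females and 5.36 in males (camera adjusted p = 1.06e-10 and 3.71e-17, and adjusted p = 0.0935 and 0.0784 with an estimated correlation). In females all 24 yolk and eggshell genes rose (median 6.41, adjusted p = 2.18e-12, and adjusted p = 0.0587 with an estimated correlation), as did 32 of 37 ovary genes (median 4.01, adjusted p = 1.06e-10, and adjusted p = 0.056 with an estimated correlation) and all 34 mitosis genes (median 3.69, adjusted p = 4.24e-14, and adjusted p = 0.0527 with an estimated correlation). Among these osk rose by 7.91 ± 0.19, pim by 7.14 ± 0.11 and Orc1 by 5.94 ± 0.12.

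In males accessory gland genes rose in 35 of 36 (median 8, camera adjusted p = 2.21e-25, and 0.000933 with an estimated correlation). Acp53C14a rose by 11.23 ± 0.13 (adjusted p = 1.89e-12), EbpII by 11.15 ± 0.17, Ebp by 11.04 ± 0.16, Acp53Ea by 10.96 ± 0.09, BG642312 by 10.60 ± 0.19 and Acp53C14b by 10.55 ± 0.18. Muscle genes rose in 18 of 26 and eye genes in 16 of 24 in males (adjusted p = 3.41e-05 and 7.49e-05, and adjusted p = 0.144 and 0.121 with an estimated correlation), with Mf at 7.55 ± 0.15, Pdh at 7.60 ± 0.13 and Arr2 at 5.88 ± 0.18. In females muscle genes fell in 20 of 26 (adjusted p = 0.00023, and adjusted p = 0.196 with an estimated correlation), although Mf rose by 4.93 ± 0.15 and Zasp66 by 4.08 ± 0.16. All 22 ribosomal protein genes fell in males (median -0.93, adjusted p = 5.12e-06, and adjusted p = 0.144 with an estimated correlation). In females 2 of them rose and 0 fell, and adjusted over the list alone 0 rose. Other lists that passed in males were olfaction and taste, with 20 of 36 higher (adjusted p = 7.49e-05, and adjusted p = 0.127 with an estimated correlation), mitosis, with 23 of 34 lower (0.0299, and adjusted p = 0.322 with an estimated correlation), heat shock, with 7 of 8 lower (0.0413, and adjusted p = 0.176 with an estimated correlation), and sex determination, with 14 of 18 lower (0.0479, and adjusted p = 0.176 with an estimated correlation). In females neuronal genes fell in 20 of 30 (adjusted p = 0.000172, and adjusted p = 0.056 with an estimated correlation). Pupal and adult cuticle genes fell in 14 of 24 (0.0119, and adjusted p = 0.196 with an estimated correlation), ecdysone genes in 20 of 31 (0.0151, and adjusted p = 0.343 with an estimated correlation), glue and storage genes in 7 of 22 (0.0178, and adjusted p = 0.244 with an estimated correlation) and hemocyte genes in 9 of 16 (0.0338, and adjusted p = 0.395 with an estimated correlation).

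The largest decreases from pupae to adults included genes named above for their rise from larvae to pupae. In females Osi12 fell by 10.40, CG31606 by 10.38, Osi4 by 9.83, Osi9 by 9.79, CG13023 by 9.77 and CG13720 by 9.67. A second CG13023 probe set fell by 0.53 in females and was not called in males (-0.38). In males CG13023 fell by 10.88, Osi9 by 10.20, mey by 10.18, the fat body gene Fbp1 by 9.74, dy by 9.63 and Osi4 by 9.39. The ecdysone-responsive gene ImpE1 fell by 6.51 in females and by 8.94 in males, and ImpL1 fell by 6.56 in females and by 8.36 in males. The other ImpE1 probe sets had smaller values, -5.26, -0.62 and -2.50 in females and -6.35, -0.69 and -1.82 in males. In all 5109 probe sets rose and 5098 fell in females, and 3521 rose and 6050 fell in males. Under array-median centring the split in females was 6134 and 3902.

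**Figure D3:**
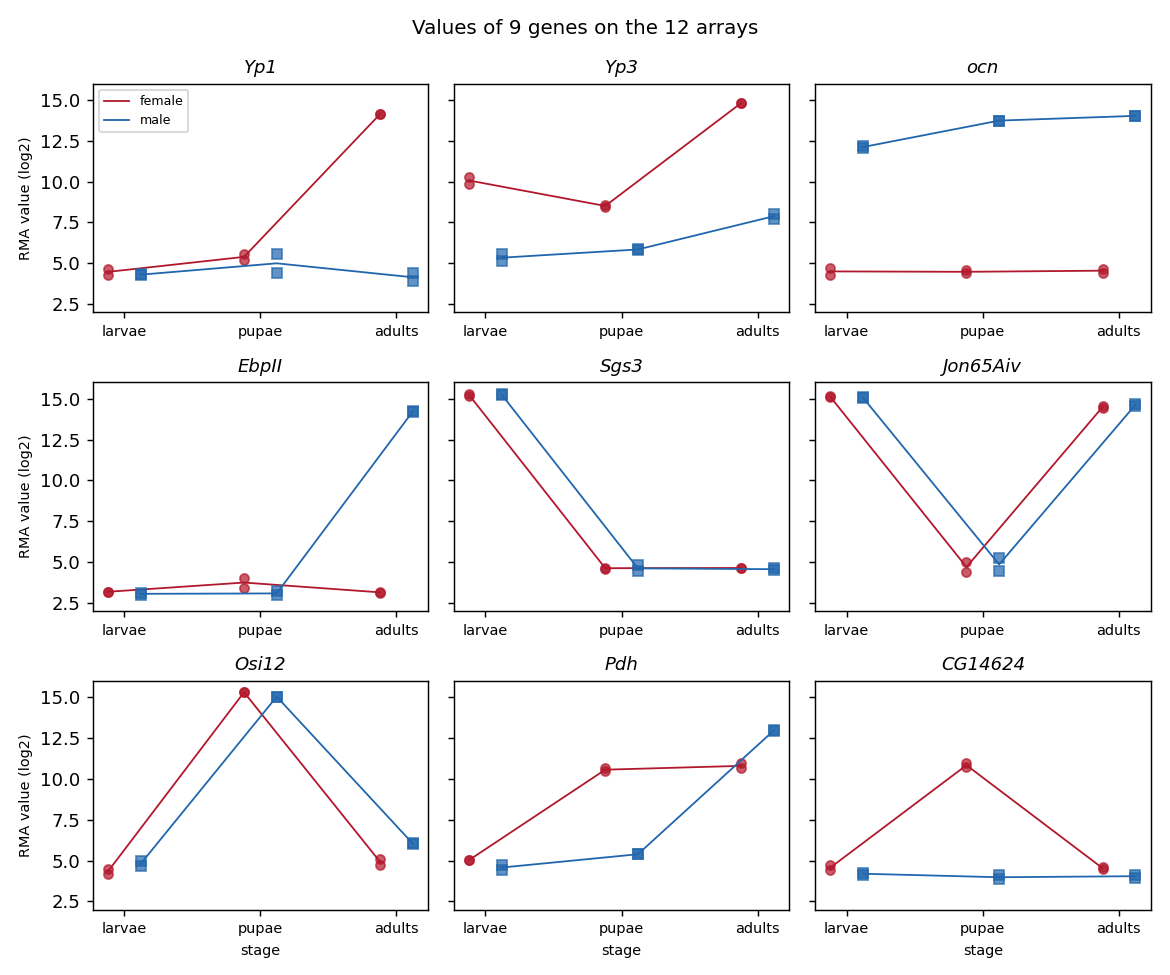
Each panel gives the RMA values (log2) of 1 gene on the 12 arrays by stage, with circles for females, squares for males and lines through the group means. Yp1 reaches a mean of 14.14 in female adults, EbpII one of 14.22 in male adults, and CG14624 one of 10.85 in female pupae.

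The change of the sex difference between stages was tested directly. From larvae to pupae 3287 probe sets changed their sex difference, 1452 towards females and 1835 towards males, with 432 and 1392 by at least 2-fold. After recentring the split was 950 and 2013, and it turned round with the filter on dim probe sets, to 1826 and 1298. The count towards females also fell when an array of any group was left out, except for female larvae replicate 2. The count towards males fell for each array left out. Of 53 testis genes 36 moved towards males and 2 towards females (median -1.53, camera adjusted p = 1.39e-14, and adjusted p = 0.0514 with an estimated correlation). Muscle genes moved towards females in 10 of 26 (median 0.51, adjusted p = 0.0146, and adjusted p = 0.806 with an estimated correlation). The largest changes towards females were in CG14624 (6.50 ± 0.22, adjusted p = 2.16e-07), CG15615, CG11693 and CG13154, and those towards males in Pen (-4.42 ± 0.13), sip2 (-3.92 ± 0.20), CG4995 (-3.53 ± 0.20) and CG31174 (-3.42 ± 0.33). Pen, an importin gene, had means of 10.82 in female and 12.12 in male larvae and of 7.60 in female and 13.31 in male pupae.

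From pupae to adults 9674 probe sets changed their sex difference, 4891 towards females and 4783 towards males. The sex difference of Yp1 changed by 9.61 ± 0.46 (adjusted p = 4.99e-08), that of dhd by 9.31 ± 0.36, of Cp36 by 9 ± 0.31 and of mtrm, a regulator of the meiotic divisions of the egg, by 8.97 ± 0.13. Towards males the changes were -11.75 ± 0.24 for EbpII, -11.44 ± 0.23 for Ebp, -11.20 ± 0.18 for Acp53C14a and -11.17 ± 0.25 for Acp63F. The sex difference of all 26 muscle genes moved towards males (median -2.27, camera adjusted p = 5.07e-10, and 0.0348 with an estimated correlation), as did that of 20 of 24 eye genes (median -1.80, adjusted p = 1.59e-06, and 0.0348 with an estimated correlation).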

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

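The tests of a dilution by ovary RNA, of developmental age on list members and of the share of pupa-specific genes were chosen only after the results were seen, as were the recentring of the arrays and the condition on single adult arrays. The results of this part were singled out because the sex difference itself changed between stages in a direct test.

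From larvae to pupae the sex difference changed in 3287 probe sets, and from pupae to adults in 9674. From larvae to pupae it moved towards females in CG14624 (6.50), CG15615 (5.51), CG11693 (5.43) and CG13154 (5.38), and towards males in Pen (-4.42), sip2 (-3.92), CG4995 (-3.53) and CG31174 (-3.42). From pupae to adults it moved towards females in Yp1 (9.61), dhd (9.31), Cp36 (9) and mtrm (8.97), and towards males in EbpII (-11.75), Ebp (-11.44), Acp53C14a (-11.20) and Acp63F (-11.17).

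Among gene lists, the median over the members of the change in sex difference was -1.53 for testis and 0.51 for muscle from larvae to pupae. From pupae to adults this median change was 6.07 for yolk and eggshell, 4.38 for ovary, 4.33 for mitosis, 1.33 for heat shock and 0.95 for ribosomal proteins. Towards males the median change was -7.98 for accessory gland, -2.27 for muscle, -1.80 for eye, -1.35 for olfaction and taste, -1.09 for neuronal, -1.02 for hemocyte, -0.72 for pupal and adult cuticle and -0.63 for digestive enzymes. With an estimated correlation the calls of yolk, ovary, accessory gland, eye, olfaction, muscle, mitosis and neuronal genes held for pupae to adults. They were lost for heat shock (adjusted p = 0.113 with an estimated correlation), ribosomal proteins (0.0835), hemocyte (0.191), cuticle (0.171) and digestive enzymes (0.279), and for testis (0.0514) and muscle (0.806) from larvae to pupae.

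A small female-higher difference ran over most probe sets in larvae and pupae, with medians of 0.23 and 0.37. The scaling of the arrays is a candidate explanation. Control transcripts of the hybridisation mix were higher on female arrays by a median of 0.43 in larvae and 0.73 in pupae, above the 0.1 set beforehand. In adults the median over all probe sets was 0.21, near that of larvae, while the controls differed by 0.011, so the shift did not follow the controls at each stage. Replicates of 1 group also differed in mean control level (11.49 and 11.93 in male pupae), and a small sex difference of many transcripts stays open and untested.

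In female pupae 16 of 24 cuticle, 19 of 24 eye and 21 of 26 muscle genes were called higher and 2, 1 and 0 lower, with camera adjusted p = 0.251, 0.088 and 0.0155, the last with an adjusted p = 0.607 with an estimated correlation. Of 771 female-higher probe sets of at least 2-fold, 51.2% stayed so after recentring, but this shifts all probe sets of an array alike, so the share cannot decide whether scaling made the differences, and scaling stays open. For developmental age, the planned r of the pupal sex difference with adults minus larvae, across 1681 genes, was -0.03 and met the bound against age, but that set held 8 of the 74 list members. On the 74 members r was 0.12, between the bounds, so age and sex cannot be told apart here. The share of the 636 female-higher genes that were also at least 2-fold above female larvae and female adults was 43.1%, which decides nothing, since these genes were chosen for high values on the same arrays and no background share was computed.

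In adult females 25 of 26 muscle, 20 of 24 eye, 21 of 36 olfactory and 18 of 30 neuronal genes were called lower, but with an estimated correlation these list calls were lost (adjusted p = 0.0716, 0.0716, 0.132 and 0.0716). For the neuronal list the estimate was 0.016 against the preset 0.01, so its loss did not come from the correlation alone. That run of the test also has fewer degrees of freedom. The control transcripts met the bound set beforehand against scaling, with a median difference of 0.011 in adults, above -0.2. The lowest control difference between single adult arrays was -0.36, against list medians of -1.56, -1.45, -0.84 and -0.64, so the margin is narrower for the olfactory and neuronal lists. As the shift over all probe sets did not follow the controls at each stage, the controls alone cannot settle scaling. That shift was 0.21 in adults, in the direction opposite to these lists. Dilution by RNA of the ovary is a candidate for the lower levels, but the test cannot decide it. Among members with a mean of at least 7, the medians of the 4 lists differed by at most 0.44, within the bound of 0.5 (permutation test, lowest adjusted p = 0.108). This floor, chosen after the results were seen, kept 25 muscle, 16 eye, 10 olfactory and 14 neuronal members. Over all members the medians ran from -1.56 to -0.64, and a test not passed on few members does not show an equal fall. Digestive enzymes, with 5 higher and 15 lower, did not fall alike, and a sex difference within these tissues stays open and untested.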

How the results depend on the processing

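Recentring was the only alternative here chosen after the data were seen. Of 363 values of named genes, 349 kept their call under all alternatives run for them, and none reversed. These genes were taken mainly for large called differences in the same data, which favours a kept call, so the share does not speak for other genes. Of 171 list tests 112 kept call and direction under all alternatives, and with an estimated inter-gene correlation 15 of 61 passing tests still passed. That alternative also has fewer degrees of freedom, so the lost calls cannot be put down to the correlation alone. In each test where an array was left out, the lone array of its group is assumed to vary like the other groups. Signal over background limits genes near the lower end of the scale, whose differences are compressed.

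A 2-fold minimum, stricter by construction, left 1851, 2720 and 7213 calls for the sex difference in larvae, pupae and adults. It left 3657 and 4446 from larvae to pupae in females and males, 5198 and 4365 from pupae to adults, and 1824 and 6260 for the changes of the sex difference. Shared sex bias of genes fell from 4073, 4843 and 2803 to 1444, 1621 and 1376 for larvae with pupae, pupae with adults and larvae with adults. The filter on dim probe sets, which tests fewer, left 3697 calls in larvae and 6981 in pupae.

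Recentring left 4175 calls between the sexes in larvae and 6693 in pupae, and 2571 and 2924 shared genes for larvae with pupae and pupae with adults, by its construction as a shift of whole arrays. Array-median centring gave 16661 in larvae. Where arrays were left out in turn the larval count ranged from 4076, without male larvae replicate 2, to 7662; the cause was not tested. The X-linked odds ratio of female-higher larval genes was 1.34 at a 2-fold minimum. That of male-higher genes was 0.683 in larvae and 0.794 in pupae with the dim filter and 0.765 and 0.823 after recentring, and from 0.79 to 0.939 in larvae with arrays left out. The call was gained with the dim filter and after recentring at both stages, and in larvae without female larvae replicate 2 (0.79) or male larvae replicate 1 (0.843); the cause was not tested.

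Over the tested probe sets replicate numbers showed no pairing of samples: deviations of same-numbered arrays correlated between -0.08 and 0.08. That check left out the control transcripts. In adults their mean level was 11.61 in females and 11.64 in males for replicate 1, and 12.04 and 11.97 for replicate 2. In larvae the male replicates were equal (11.73), and in pupae the female ones were nearly so (12.31 and 12.3). A pairing at the hybridisation step therefore stays open for adults. With the replicate block 7058, 12258 and 12267 probe sets were called between the sexes in larvae, pupae and adults, and among named genes only the change of msl-2 from male pupae to adults lost its call.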

Other observations

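Some genes of the immune and stress response differed between stages and sexes. BomS2 rose from pupae to adults by 5.94 ± 0.27 in females and 7.48 ± 0.27 in males, and TotC rose in males by 5.39 ± 0.26. In larvae Drs was lower in females (-1.23 ± 0.27) and CecB higher (1.15 ± 0.14). PGRP-SC2 fell from larvae to pupae by 4.12 in females and 4.16 in males. Of the 17 measured antimicrobial genes 3 were higher and 5 lower in adult females, and the list did not pass the camera test (adjusted p = 0.472).

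Members of the glue and storage protein list and an odorant-binding protein gene changed with stage. Fbp2 fell from pupae to adults by 8.89 in females and 9.25 in males, and Lsp2 by 5.09 in females. Obp56d fell from larvae to pupae by 7.81 in females and 8.69 in males and rose from pupae to adults by 5.79 ± 0.17 and 7.74 ± 0.17. Probe sets for the 3′ and 5′ ends of actin differed by between 0.37 and 0.77 on the 12 arrays, with the highest values, 0.72 and 0.77, in male adults. For Gapdh the difference lay between 0.73, in a female larval array, and 1, in a female adult array. For eIF4a it lay between 1.09 and 1.1 in pupae, 1.25 and 1.36 in larvae and 1.44 and 1.59 in adults.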
